A study of Drosophila melanogaster with 2 samples.

How the data were processed

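Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos aged 8 to 24 h, per the source name in the labels. The labels' separate age field holds a number of hours far above that range for both samples and was not used. The flies carried a transgene for CG32532 fused to enhanced green fluorescent protein, and an antibody against GFP pulled down the fusion protein with the DNA attached to it. Chromatin was sheared by sonication to 200 to 800 bp, per the labels. The labels describe 2 biological replicates of 1 group, replicate 1 and replicate 2, so no comparison between conditions exists and the replicates could be compared only with each other. A control is named in the labels and was not used here.

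The files are peak lists on assembly dm6, per the labels. Per the file headers in the accompanying notes, peaks were ranked by the irreproducible discovery rate (IDR), which measures how well the rank of a peak repeats between 2 lists, and the thresholded sets derive also from 1 further file whose content is not given in the sources used here. The aligner, the peak caller and their versions are not given in the sources used here. The deposited score of each peak is the IDR on a scale on which 830 stands for an IDR of 0.01, and every thresholded set holds only scores of 830 or more. The deposited signal value is the strength of the peak as the authors' caller gave it. What it measures and its scale are not stated, so it was used to rank peaks within a list, to correlate the replicates and as a multiple of the median peak. The deposited −log10 q values and the -log10 of the IDR entered no comparison. Peaks in the lists of each replicate were called by the authors on that replicate alone, and those of the series-level lists have the values of calls on both replicates pooled. The series-level ranked lists hold 16 further columns of per-replicate values with no name, which were not used. The files give no read counts, so the depth of each library is unknown and no interval that needs it is given.

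The main set is the conservative thresholded set of 5325 peaks, called the replicated set, which by its name and source files rests on both replicates. The other series-level set has 7718 peaks and is called the optimal set. The signal of a replicated peak in each replicate was taken from the strongest overlapping peak in that replicate's ranked list. It was divided by the median of that replicate over the replicated peaks, and the mean and SD of both values are given as multiples of the median peak. Coordinates are on dm6 and count from 1. Genes came from Ensembl release 115 on the same assembly, without transposable elements (18277 genes, of which 13968 are protein-coding). Every peak used lay within the arms 2L, 2R, 3L, 3R, 4, X and Y, and peaks on other sequences (7 of replicate 1 and 1 of the optimal set) were left out of tests of location, motifs and genes.

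The tests, gene lists, motifs and the rule for naming genes given here were fixed before the data were examined. Overlap of the replicates' sets (at least 1 bp) was compared with 1000 random placements of the replicate 2 peaks on the same arms, one-sided. Summits were classed in order as within 500 bp of a transcription start site (TSS), coding exon, untranslated or noncoding exon, intron or intergenic, and compared with 1000 random placements on the same arms, two-sided. Peaks per arm were compared with the arm's share of sequenced bases by an exact binomial test. For 15 motifs, 200-bp windows centred on summits were compared by Fisher's exact test, two-sided, with control windows matched on arm, class and GC content within 2 percentage points, and 5324 summits had a control. The same test compared the strongest 1331 with the weakest 1331 replicated peaks. For 24 gene lists, the number of genes nearest by TSS to at least 1 replicated summit was compared with 10000 random lists matched on 10 groups of nearest-TSS territory length, two-sided, where the territory is the stretch nearer to a gene's TSS than to any other. Peaks were assigned to protein-coding genes, and for the tRNA list to protein-coding and tRNA genes. P-values were adjusted by Benjamini-Hochberg within each family (5 classes, 7 arms, 15 motifs, 24 lists), with a threshold of 0.05. These p-values compare peaks or genes with random ones and do not measure the spread between replicates. The smallest p that the permutations can give is 0.001 for the overlap, 0.002 for the classes and 0.0002 for the lists. For 3 list symbols the current name was used.

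The genes named are CG32532, the nearest protein-coding genes of the 15 strongest replicated peaks, the 10 genes nearest to most replicated peaks with ties broken by summed signal, and in each list the 4 bound genes with the strongest peak where the list passed the threshold and the 2 strongest where it did not. The tests were tested on simulated data. Random sites gave 0 class calls in 10 sets of 5000 sites. A TSS share of 30.3% was recovered as 30.6%, and a TAATTA share of 21.2% was recovered as 21.1%. In 230 list tests on random sites over 13968 genes, matching on territory gave 3 calls where Fisher's test with no match gave 93. The tRNA list was not among these. The random sites lay on 2L, 2R, 3L, 3R and X and did not have the lean of the peaks to TSS. Among 1300 simulated windows per group that differed in GC alone, TAATTA was called without pairing and was not called in 708 pairs of equal GC. Whether a true difference in TAATTA would survive the pairing was not simulated.

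Alternatives were the optimal set, each replicate's own thresholded set (which leaves out the other replicate), the strongest 2662 peaks, peaks held by both replicates' sets, other overlap rules, a promoter window of 1000 bp, protein-coding genes alone, 100-bp windows, windows 1000 bp from the summits, dinucleotide-shuffled windows, summits within 1000 or 10000 bp of a TSS, and a list test with no match. Merging of overlapping peaks, pairing of strong and weak windows at equal GC within 2 percentage points over 200 or 50 bp, a CTCF-type motif and a list of mitochondrial ribosomal protein genes were added after seeing the data. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.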

Results

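Binding of the CG32532 protein was mapped by ChIP-seq in whole fly embryos aged 8 to 24 h, in 2 biological replicates. CG32532 is an X-linked gene for a predicted paired-class homeodomain protein, a family of DNA-binding proteins that recognise TAAT-type sequences. The replicated set held 5325 peaks with a median width of 360 bp, and together they covered 1.16% of the sequenced arms. Replicate 1 alone gave 3957 peaks past the same IDR score and replicate 2 gave 6850. Each of these sets was called on 1 replicate, so its IDR does not measure agreement between the replicates, unlike that of the replicated set. The peak lists carry no read counts, so the depth of each library is unknown.

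The replicates were compared first. Of the 3950 replicate 1 peaks on the arms, 3360 (85.1%) overlapped a replicate 2 peak, and random placement gave 113 ± 10.4 (SD over 1000 draws; one-sided permutation p = 0.001, the smallest the draws can give). Of the 6850 replicate 2 peaks, 3410 (49.8%) overlapped a replicate 1 peak. The placements spread peaks evenly over each arm, while 58.9% and 52.8% of the replicates' own summits lay within 500 bp of a TSS. The p-value therefore does not show agreement beyond a shared lean to gene starts. Both replicates' own sets held 3355 of the replicated peaks (63.0%). A further 1344 were held by the replicate 2 set and not by that of replicate 1, 223 were held the other way round, and 403 were held by neither. Over the 5279 replicated peaks found in both ranked lists, the signal values had a Spearman rho of 0.745 and a Pearson r of 0.845 on the log2 scale. This correlation is across peaks, which are not independent replicates, in a set selected for agreement. The log2 ratio of the replicates' signals had an SD of 0.55 across peaks.

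**Figure D1:**
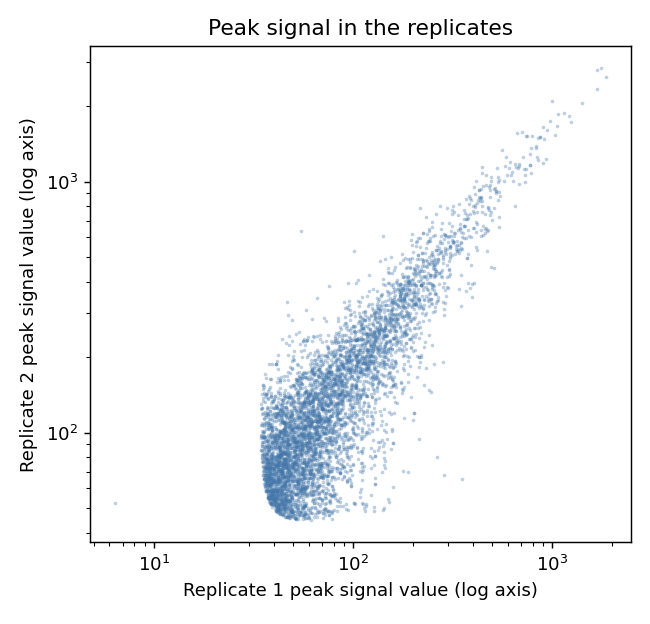
Signal value of each replicated peak in replicate 1 (x axis) and replicate 2 (y axis), both on log axes in the caller's units, 1 point per peak for 5279 peaks. Points follow a rising band with a Spearman rho of 0.745, with sharp lower edges in this set of peaks that passed the IDR threshold.

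Summits lay mainly at gene starts. Of the 5325 replicated peaks, 2986 (56.1%, exact 95% binomial interval 54.7 to 57.4%) had their summit within 500 bp of a TSS, 4.12 times the 13.6% of random placement. Coding exons were nearly empty, with 49 summits (0.92% against 13.9%). Untranslated or noncoding exons held 2.03% against 5.86%, introns 30.1% against 39.5% and intergenic sequence 10.9% against 27.2%. All 5 classes differed from random placement (adjusted permutation p = 0.002 each, the smallest the draws can give). The classes exclude each other, so the excess at TSS by itself lowers the shares of the other classes. Of these other classes introns fell least below random placement (0.762 times), against 0.401 times for intergenic sequence, 0.346 for untranslated or noncoding exons and 0.0663 for coding exons. Summits outside the TSS class were not compared with random placement on their own, so the lower intron share does not show that introns were avoided. The replicates' own sets gave a TSS share of 55.8% ± 4.31 (SD, n = 2), so the distance to random placement was larger than the spread between replicates. Of the 2845 summits within 500 bp of a protein-coding TSS, 2240 (78.7%) lay upstream of it, and the median offset was -86 bp. Of the strongest 1331 peaks 62.3% lay at a TSS, and of the weakest 1331 peaks 49.3%.

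**Figure D2:**
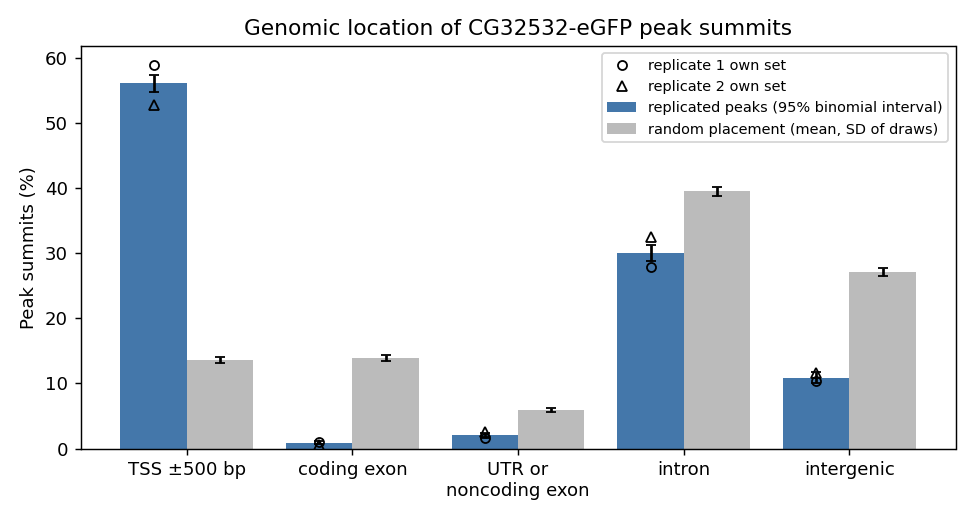
Share of peak summits (y axis, %) in 5 annotation classes (x axis) for the 5325 replicated peaks (blue, exact 95% binomial interval), random placement on the same arms (grey, mean and SD of 1000 draws) and each replicate's own set (open symbols). The TSS class holds 56.1% of summits against 13.6% by random placement, and the replicates' own sets lie at 58.9% and 52.8% there.

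Peaks were spread over the large arms and were scarce on chromosomes 4 and Y. Arm X had 44.3 peaks per Mb, 1.14 times its share of bases (exact binomial adjusted p = 9.69e-06). Chromosome 4, a small and largely heterochromatic chromosome, had 3 peaks (2.25 per Mb, 0.058 times its share; exact adjusted p = 4.05e-18), and Y had 0 (exact adjusted p = 6.30e-58). Arm 2L had 41.5 per Mb (exact adjusted p = 0.0465), and this call ended in 4 of 6 alternatives, replicate 1's own set among them (exact adjusted p = 0.101). Arms 2R, 3L and 3R did not pass the threshold. The arms were not compared with 4 and Y left out, and how well reads can be placed on 4 and Y was not tested. On chromosome 4 the replicate 1 set had 2 peaks and the replicate 2 set 25 (0.376 times its share).

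The tagged gene itself had weak peaks, and a tagged transgene copy may raise signal over this locus, which was not tested. CG32532 (X, 19531851 to 19547482, minus strand) was the nearest protein-coding gene of 2 replicated peaks. The first (X, 19546764 to 19547123, summit 19546944) lay in an intron, 538 bp into the gene, with a signal 0.72 ± 0.079 times the median peak (SD, n = 2), rank 4099 of 5325. Its summit sequence was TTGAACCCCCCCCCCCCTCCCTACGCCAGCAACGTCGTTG (X, 19546924 to 19546963). It was held by the replicate 2 set and not by that of replicate 1. The second (X, 19550061 to 19550420, summit 19550241) was intergenic, 2759 bp upstream, with signal values of 70.1 in replicate 1 and 52.6 in replicate 2, rank 4157. Both replicates' sets held a peak there.

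Of the 15 strongest peaks of the replicated set 12 lay at a TSS, and all 15 were held by both replicates' own sets. This order holds within that set: intronic peaks at cbt (2L, summit 481079) and Lk6 (3R, summit 11761043) passed the IDR score but are not in it, and their pooled signals of 3976 and 2756 were above that of the 15th peak (2561). Both were named after their values were seen. The highest was at Ugalt, a UDP-galactose transporter (X, summit 2703893, 41 bp upstream of the TSS), with 25.2 ± 1.16 times the median peak (SD, n = 2). Its summit sequence was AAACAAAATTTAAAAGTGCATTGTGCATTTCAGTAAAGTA (X, 2703873 to 2703912). An intronic peak of CG11050 (2L, summit 6612710) reached 24.5 ± 0.56 times and the promoter of CG14100 (3L, summit 19590615) 24.96 ± 3.56 times. Genes for mitochondrial ribosomal proteins had 3 of the 15, namely mRpL41 (2R, summit 15217748; 22.5 ± 3.24 times), mRpS10 (3R, summit 15229539; 15.9 ± 0.15 times) and mRpL23 (3L, summit 2373597; 14.2 ± 1.34 times). Others were Tcs5 (19.2 ± 2.19 times), the translation factor eIF6 (16.6 ± 2.45 times), CenG1A, CG5611, the Polycomb group gene ph-p, the mitochondrial RNA-processing enzyme PNPase, CG7601 and, in introns, CG9663 and CG32772.

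Several genes were nearest to many peaks, counted with no match on territory length, and long territories gather more peaks by chance. CHES-1-like, a forkhead-type gene on X, was nearest to 18 replicated peaks, the strongest in an intron (summit 7706996; 7.98 ± 0.94 times the median peak). CG6163 had 12, Tlk and CG43245 had 11 each, and dnc, CG32264, shn and Mob2 had 10 each. The genes px and Hipk had 9 each. The kinase gene Tlk held the strongest peak among these (X, summit 3742214; 12.4 ± 0.96 times). At Mob2 the strongest peak was at 0.95 ± 0.40 times the median. These numbers depended on the library: in replicate 1's own set CG6163, Tlk and CG43245 had 7 peaks each, dnc and shn 6 each, px 5 and Mob2 2, and in that of replicate 2 shn had 18. CHES-1-like had 16 and 20 peaks in the replicates' own sets. The strongest peaks nearest to CG6163 and CG43245 lay 15486 and 19131 bp from the TSS of these genes. In all, 3456 of 13968 protein-coding genes were nearest to at least 1 peak, and 112 genes had 5 or more.

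Cytoplasmic ribosomal protein genes had the highest share bound of the 24 lists in the replicated set. Of 92 genes, 66 (71.7%) were nearest to a peak, 3.52 times the 18.8 ± 3.78 of territory-matched random lists (adjusted permutation p = 0.0012, from the smallest p the draws can give). The share was 70.7% ± 3.07 across the replicates' own sets (SD, n = 2). In replicate 2's own set it was 72.8%, and developmental signalling genes had a higher share there (75.7%). The ribosomal protein list passed in all 9 alternatives, with folds from 1.34, where summits up to 10000 bp from a TSS counted, to 5.01 in the strongest 2662 peaks. The strongest were at the TSS of RpL7 (2L, summit 10201051; 5.71 ± 2.58 times the median peak), RpS27 (5.61 ± 2.38 times), RpL34b (5.42 ± 1.15 times) and RpL23A (4.71 ± 1.84 times). All of these stood higher relative to the median in replicate 1. RpL7 had signals of 511 in replicate 1 and 451 in replicate 2, where the medians over peaks in both ranked lists were 67.8 and 116. Genes of the proteasome, the protein-degrading complex, were bound in 12 of 48 cases (adjusted permutation p = 0.84), with Rpn3 and Rpn6 the strongest. That list holds 16 paralogs marked T or R in the symbol, such as Prosalpha3T and Rpt3R, of which those marked T are known from the testis, and 2 of the 16 and 10 of the 32 others were bound. Heat shock genes were bound in 6 of 19 cases (adjusted permutation p = 0.86), among them Hsp27 (6.91 ± 0.34 times) and Hsp83.

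Fewer genes than in random lists were bound in 3 lists. Cuticle protein genes had 7 of 111 bound against 24.6 ± 4.34 (adjusted permutation p = 0.0012; folds from 0.064 to 0.53 over 9 alternatives). The strongest were at Cpr76Ba, Cpr65Ec, Cpr and Cpr64Ad, and Cpr, matched by its symbol, is the gene for cytochrome P450 reductase and not for a cuticle protein. Of the histone genes 1 (0.870%) was bound against 15.4 ± 3.58 (adjusted permutation p = 0.0012; folds from 0.035 to 0.12 over 9 alternatives). Most of them are copies in a tandem array, where short reads are hard to place, and the bound one was the separate variant gene His3.3B. The random lists drew genes singly, so side-by-side copies counted as independent genes, which can make the SD and p too small. How far neighbouring cuticle protein or tRNA genes share this limit was not tested. tRNA genes had 32 of 290 bound against 56.7 ± 6.44 (adjusted permutation p = 0.0012), and of 9 alternatives this call ended in replicate 2's own set alone (fold 0.82, adjusted permutation p = 0.25). Their share bound was 6.90% in replicate 1's own set and 18.6% in that of replicate 2. The strongest were nearest to tRNA:Lys-TTT-1-1 (2L, summit 8292628; 5.62 ± 1.41 times the median peak), tRNA:Ile-TAT-1-2, tRNA:Tyr-GTA-1-8 and tRNA:Asn-GTT-1-1, at distances from 208 bp to 10977 bp.

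Lists of developmental and neuronal genes did not pass the threshold (adjusted permutation p from 0.14 to 1). The list of paired-class homeobox genes holds CG32532 itself and also Poxm and Poxn, which are counted there as paired-box genes. It had 4 of 28 bound against 9.55 ± 2.48 (adjusted permutation p = 0.14). The strongest were PHDP (1.32 ± 0.52 times the median peak) and Poxm (0.97 ± 0.15 times). The share of this list bound was 10.7% in replicate 1's own set and 35.7% in that of replicate 2. Hox genes had 5 of 8 bound, among them Antp and Ubx in introns. Anterior head genes had 4 of 15 bound (slp2, ems), neuroblast and temporal factors 4 of 23 (grh, hb) and neuron identity factors 8 of 22 (zfh1, vvl). Neuroblast and temporal factors were bound at 4.35% in replicate 1's own set, where alone they passed the threshold (fold 0.147, adjusted permutation p = 0.0269), and at 34.8% in that of replicate 2, and their fold reached 0.804 among the 9 alternatives. Axon guidance genes had 17 of 35 bound, among them PlexA, 1 of the 3 peaks on chromosome 4, and side. This list passed with no match on territory (fold 1.963). Synapse genes had 7 of 30 bound, and the pan-neuronal RNA-binding protein gene elav had a peak of 6.53 ± 0.65 times the median at its TSS (X, summit 523485) besides Syx1A. Developmental signalling genes had 16 of 37 bound (spi, aos). This list passed in replicate 2's own set (fold 1.73, adjusted permutation p = 0.0024) and in the optimal set.

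Lists of tissue and other genes did not pass either. Glia genes had 7 of 14 bound, with moody (9.72 ± 1.59 times the median peak) and Gs2 the strongest. Mesoderm and muscle genes had 13 of 31 bound, among them Mef2 with 7 peaks (strongest 5.13 ± 1.82 times) and Msp300. Tracheal genes had 5 of 11 bound (vvl, crb), gut and endoderm genes 6 of 13 (org-1, bin), hemocyte and fat body genes 3 of 13 (ush, crq), germ line genes 2 of 10 (ovo, piwi) and epidermal differentiation genes 3 of 13 (ovo, grh). Neuropeptide genes had 5 of 24 bound (amn, Proc), circadian clock genes 3 of 10 (Pdp1, cwo) and phototransduction genes 1 of 16, where norpA had a peak of 10.7 ± 0.13 times the median. Their adjusted permutation p ranged from 0.30 to 1. Over all 24 lists, the share bound was higher in the larger replicate 2 set in 22, and in 13 of them it was more than 1.5 times that in the replicate 1 set. The share of neuropeptide genes, 20.8% in the replicated set, was lower in the own sets of replicate 1 (8.33%) and replicate 2 (12.5%).

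**Figure D3:**
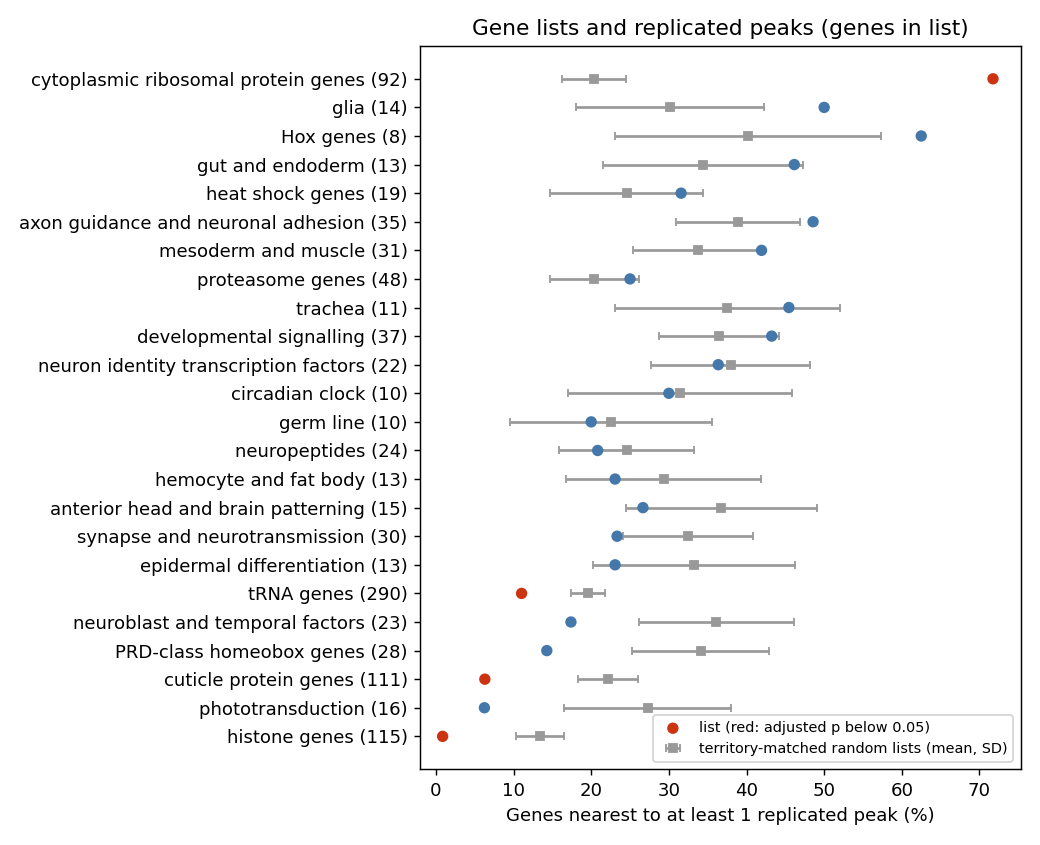
Share of genes nearest to at least 1 replicated peak (x axis, %) for 24 lists (y axis, number of genes in brackets); circles are the lists (red past the adjusted threshold) and grey squares the mean and SD of 10000 territory-matched random lists. Ribosomal protein genes reach 71.7%, and histone, cuticle protein and tRNA genes lie below their random lists.

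Of 15 motifs 4 were more frequent in peaks than in matched windows. The DREF site TATCGATA, bound by a factor of replication and growth genes, stood in 4.51% of summit windows against 1.22% of matched windows (odds ratio 3.80, 95% interval 2.88 to 5.005; Fisher's exact test, adjusted p = 3.34e-24), and its odds ratio ran from 2.60 to 16.2 over 9 alternatives, highest against shuffled windows. Motif 1 of fly promoters, GGTCACACT, stood in 2.01% against 0.73% (odds ratio 2.76, exact adjusted p = 6.54e-08), a call that ended in the strongest 2662 peaks (odds ratio 1.88, exact adjusted p = 0.122; 1.88 to 31.3 over 9 alternatives, highest against shuffled windows). GAGAG (25.2% against 19.5%, exact adjusted p = 1.33e-11) and CAGCTG (9.64% against 7.29%, exact adjusted p = 5.75e-05) were more frequent too, and CAGCTG was not against windows 1000 bp from the same summits (odds ratio 0.99). The homeodomain core TAATTA stood in 15.2% of peak windows and 15.1% of matched windows (odds ratio 1.00, 95% interval 0.90 to 1.12, exact adjusted p = 0.957). Against windows 1000 bp away, which are not matched on GC content, its odds ratio was 1.35 (exact adjusted p = 7.54e-09). TAATTA holds no G or C, so matching on GC may also remove part of an excess of the motif itself. Palindromic sites TAATNNNATTA (odds ratio 1.25, exact adjusted p = 0.241) and TAATNNATTA (1.24, exact adjusted p = 0.268) did not pass. Each passed in 4 of 9 alternatives, among them the peaks held by both replicates' sets (odds ratios 1.59 and 1.69).

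**Figure D4:**
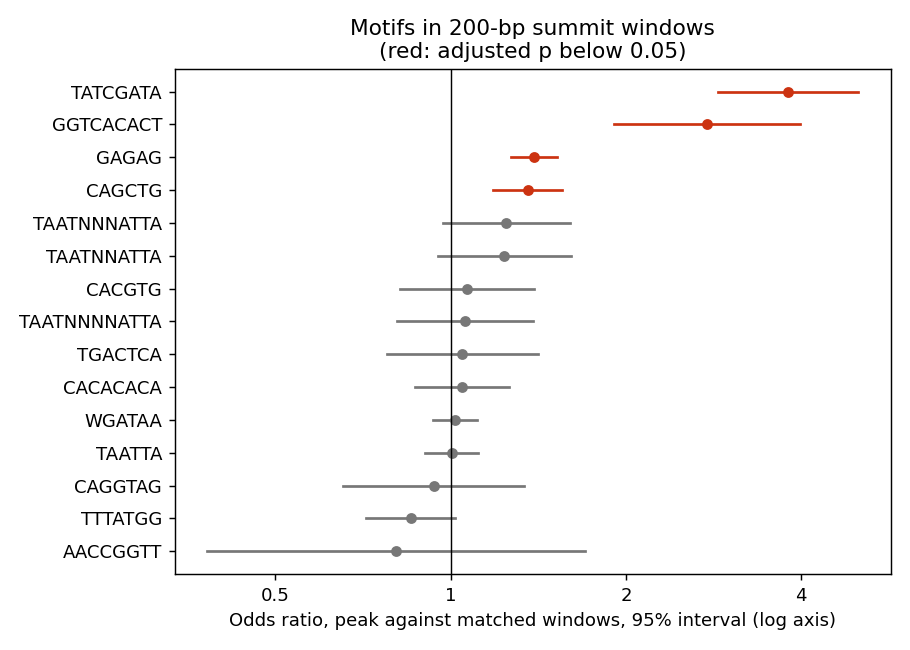
Odds ratio of each of 15 motifs in 200-bp summit windows against matched control windows (x axis, log axis, with 95% interval; y axis, motif), red where the adjusted p is below 0.05. TATCGATA lies highest at 3.80, and TAATTA lies at 1.00.

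Motif content differed between strong and weak peaks, as did GC content at the summit, which averaged 31.9% over 50 bp in the strongest 1331 peaks and 43.4% in the weakest 1331. TAATTA stood in 17.8% of the strongest 1331 windows and in 10.9% of the weakest 1331 (odds ratio 1.77, Fisher's exact test, adjusted p = 3.30e-06), a call that ended in replicate 1's own set (odds ratio 1.41, exact adjusted p = 0.065) and within the strongest 2662 peaks (1.09). It also ended when strong and weak windows were paired at equal GC, over 200 bp (838 pairs, 15.6% against 15.04%, odds ratio 1.05, 95% interval 0.803 to 1.36, exact adjusted p = 0.911) and over 50 bp (822 pairs, odds ratio 1.14). TAATTA holds no G or C, so pairing on GC may also remove part of a difference in the motif itself. The palindromic sites TAATNNNATTA, TAATNNATTA and TAATNNNNATTA did not pass (odds ratios 1.60, 1.95 and 1.85, exact adjusted p = 0.124, 0.0522 and 0.0671). All 3 passed in replicate 2's own set (2.97, 2.01 and 2.09) and in the optimal set (2.33, 2.91 and 2.32), and none did in replicate 1's own set (1.20, 1.60 and 1.24) or in pairs of equal GC. Without such pairing WGATAA was more frequent in strong peaks (28.1% against 22.6%, exact adjusted p = 0.00399). CACACACA (1.95% against 8.04%, exact adjusted p = 2.99e-12), GAGAG (22.8% against 28.8%, adjusted p = 0.00229) and GGTCACACT (0.83% against 2.48%, adjusted p = 0.00399) were less frequent. In the pairs of equal GC the odds ratios of WGATAA (0.898 and 0.872) and GAGAG (1.20 and 1.07) lay on the other side of 1 with no call, while GGTCACACT (0.249 and 0.276) and CACACACA (0.425 and 0.337) passed in both. Of 8 alternatives, 5 ended the call in each of WGATAA and GAGAG, 3 that of GGTCACACT and 1 that of CACACACA. The number of motifs past the threshold, 5 of 15, ranged from 0 to 9 between settings, with 1 in replicate 1's own set and 9 in that of replicate 2.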

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

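Of the tests in this part, those of promoter location, of TAATTA sites and of the TSS share were set out before their results were seen, and those of promoter location for GGTCACACT, promoter activity, flank GC and shoulder peaks only after.

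Some peaks that passed the IDR score in a series-level ranked list were missing from the thresholded set made from it, so no test of location, motifs or gene lists above used them. There were 136 such peaks for the replicated set and 198 for the optimal set. Of the 136, 87 lay on 3R and 34 on 2L. With peaks up to 200000 bp apart joined they made 50 regions, of which 24 held a single peak. Among the other 26 were 13 peaks at tara (3R, 16224355 to 16255470), 6 at Kdm2 (3R, 9048268 to 9057725) and 5 at cbt (2L, 471120 to 482104), where 1 intronic peak had a pooled signal of 3976. The gene Lk6 had a single intronic peak of 2756. Of the list genes counted as not bound above, 4 were nearest to such peaks: RpL13A (1 peak, strongest signal 377), the heat shock gene Hsp70Ba (2 peaks, 334), the muscle gene Tm1 (1 peak, 200.4) and the rhodopsin gene Rh5 (4 peaks, 519). These genes were named after their values were seen, and why the peaks are missing was not tested.

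The promoter motifs form the first pattern weighed: against windows matched on GC, TATCGATA and GGTCACACT were enriched and TAATTA was not. Promoter location alone would make a site as frequent at the same offset from the TSS of other protein-coding genes. The controls were genes with no summit within 1000 bp of the 1 TSS used for each, and they were not matched on GC. For TATCGATA the odds ratio against these was 2.04 (95% interval 1.62 to 2.56). This argues against location as its whole cause but leaves a GC difference open. For GGTCACACT the odds ratio was 1.17 (95% interval 0.872 to 1.56, exact adjusted p = 0.443), so promoter location may account for that motif. A general pull-down of active promoters stays open. Ribosomal protein genes were bound more often than proteasome genes without the T and R paralogs (odds ratio 5.38, Fisher's exact test p = 0.000102). This comparison was set out after its result was seen and cannot decide the question, since promoter activity was not measured. A general pull-down therefore cannot be told apart from binding by CG32532. No biological explanation was tested, since the design has 1 group.

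The second pattern is the GC content at the summits, which averaged 31.9% over 50 bp in the strongest 1331 peaks and 43.4% in the weakest 1331. Without windows holding TAATTA the difference was -11.7 percentage points (95% bootstrap interval -12.7 to -10.7), and within intron peaks, the smaller of the values for TSS and intron peaks, it was -10.2, so neither TAATTA sites nor the share of promoters accounts for it. GC bias of the sequenced fragments may contribute, since sequence 100 to 250 bp from the summit was also lower in GC, with a difference of -0.51 percentage points (interval -1.01 to -0.031). That flank difference is far smaller than the one at the summit (-11.5), sequence 400 to 600 bp away had a higher median GC in the strongest peaks (44.0% against 41.75%), and no control library was analysed here to settle it, nor was a biological explanation tested.

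The third pattern is a group of 116 replicated peaks with a signal under 20, where the median is 177. Of these, 94 (81.0%) overlapped another pooled peak with a signal of 100 or more, against 166 of the 5209 others (3.19%; Fisher's exact test p = 7.10e-109). These 94 may be shoulders of those stronger peaks, the low peaks with no such neighbour stay open, and no biological explanation was tested.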

How the results depend on the processing

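The alternatives and tests here were set before the data were examined, except the merging of overlapping peaks and the pairing of strong and weak windows at equal GC, which were chosen after. Of 564 alternative values with a test, 81 changed direction. Of the rest, 431 kept their side of the threshold, 20 no longer passed and 32 newly passed. The rest hold the 8 values of AACCGGTT by strength, whose odds ratio of 1 in the replicated set gave no direction to change. The 564 values count the TSS class both as a share and as a fold. Of those 81, 5 also lost a call: CAGCTG in peaks against windows 1000 bp away, and GAGAG and WGATAA by strength in both pairings at equal GC. Together with the 20 that did not change direction, 25 calls were lost in all. Another of the 81 newly passed the threshold: in the optimal set TATCGATA was more frequent in strong peaks (odds ratio 1.60, exact adjusted p = 0.0223), where the replicated set gave 0.98 with no call and the peaks held by both replicates' sets gave 0.489 with a call the other way. The overlap of the replicates (72.7 to 83.0% of replicate 1 peaks) and the TSS share (50.8 to 66.3% of summits) passed under every alternative run. The calls for ribosomal protein, cuticle protein and histone genes, for TATCGATA and GAGAG in peaks and for chromosomes 4 and X did so too. The overlap was each time set against placement that did not keep the lean of the peaks to TSS. Most histone genes are copies in a tandem array, a limit that every peak set shares. The list test counted such copies as independent genes under every setting. The files give no read depth, so what depth limits could not be tested, and leaving out a replicate leaves the other's own set with no test between samples.

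The replicated peak number was 2662 in the strongest peaks kept and 3355 where both replicates' sets had to hold the peak, both fewer by construction. CG32532 was nearest to 0 peaks and 1 peak there, and to 1 to 3 with each replicate left out in turn. The number of motifs past the threshold in peaks was 8 against windows 1000 bp away, and 5 to 7 with each replicate left out. By peak strength it was 9 in the optimal set, 0 in the strongest 2662 peaks, 2 in pairs of equal GC over 200 bp and also over 50 bp, and 1 to 9 with each replicate left out. The odds ratio of TAATTA in peaks was 0.978 with 100-bp windows, 0.952 against shuffled windows and 1.35 against windows 1000 bp away, where alone it passed. CACACACA in peaks, at 1.05 with no call in the replicated set, passed in 3 of 9 alternatives: against shuffled windows (odds ratio 4.81, exact adjusted p = 1.24e-29), in the optimal set (1.31, exact adjusted p = 0.00185) and in replicate 2's own set (1.38). The number of peaks nearest to a gene moved by more than 1.5 times in 23 of 71 named genes in replicate 1's own set and in 15 in that of replicate 2, in 25 in the strongest 2662 peaks, 20 in those held by both replicates' sets, 11 in the optimal set and 4 with overlapping peaks merged. The signal correlation was 0.729 in the strongest 2662 peaks and 0.659 in the optimal set. The pairs of equal GC also held fewer windows (838 and 822 of 1331 in each group). For these motif counts, TAATTA and the correlation the cause was not tested.

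Values that crossed 1 follow, and the cause was not tested. In the optimal set, the peak-to-control odds ratio was 2.22 for AACCGGTT and 0.955 for CACGTG. The strong-to-weak odds ratio was 1.06 for CAGGTAG, 1.60 for TATCGATA and 0.729 for TGACTCA. The list fold was 1.77 for germ line, 0.996 for heat shock, 1.01 for hemocyte and fat body and 1.20 for neuron identity transcription factors. The density fold was 1.03 for 2R. In the strongest 2662 peaks, the peak-to-control odds ratio was 0.820 for CACACACA, 0.841 for CACGTG, 1.34 for CAGGTAG, 0.822 for TGACTCA and 0.983 for WGATAA. The strong-to-weak odds ratio was 1.07 for CACGTG and 0.9498 for TAATNNNATTA. The list fold was 1.54 for circadian clock, 1.47 for germ line and 0.846 for proteasome. In the 3355 peaks held by both replicates' sets, the peak-to-control odds ratio was 1.15 for AACCGGTT, 0.851 for CACACACA, 1.22 for CAGGTAG and 0.997 for WGATAA. The strong-to-weak odds ratio was 0.843 for TGACTCA. The list fold was 0.907 for axon guidance and neuronal adhesion, 1.22 for germ line, 0.945 for gut and endoderm and 0.981 for proteasome. The density fold was 1.01 for 2R. With overlapping peaks merged, the peak-to-control odds ratio was 0.954 for CACGTG and 1.17 for CAGGTAG. With 100-bp windows, the peak-to-control odds ratio was 1.36 for AACCGGTT, 0.794 for CACACACA, 1.52 for CAGGTAG and 0.978 for TAATTA. Against windows 1000 bp away, the peak-to-control odds ratio was 0.865 for CACACACA, 0.824 for CACGTG, 0.994 for CAGCTG and 0.919 for TGACTCA. Against shuffled windows, the peak-to-control odds ratio was 0.855 for CACGTG, 1.12 for CAGGTAG, 0.952 for TAATTA, 0.778 for TGACTCA and 0.929 for WGATAA. In pairs of equal GC over 200 bp, the strong-to-weak odds ratio was 1.09 for CAGCTG, 1.20 for GAGAG, 0.879 for TAATNNNATTA and 0.898 for WGATAA. In pairs of equal GC over 50 bp, the strong-to-weak odds ratio was 1.06 for CAGCTG, 1.07 for GAGAG, 0.919 for TGACTCA and 0.872 for WGATAA. With no match on territory, the list fold was 1.08 for anterior head and brain patterning, 1.21 for circadian clock and 1.47 for neuron identity transcription factors. With summits within 1000 bp of a TSS, the list fold was 0.488 for Hox, 1.05 for germ line and 0.756 for mesoderm and muscle. With summits within 10000 bp of a TSS, the list fold was 0.818 for Hox, 0.973 for axon guidance and neuronal adhesion, 1.10 for circadian clock, 1.37 for germ line, 1.07 for hemocyte and fat body, 0.991 for proteasome and 0.938 for trachea. With each replicate left out in turn, the peak-to-control odds ratio ranged from 0.759 to 1.58 for AACCGGTT, 0.877 to 1.38 for CACACACA, 1 to 1.18 for CAGGTAG and 0.993 to 1.38 for TAATNNNNATTA. The strong-to-weak odds ratio ranged from 0.678 to 1.30 for CACGTG, 1.10 to 1.39 for TATCGATA and 0.960 to 1 for TGACTCA. The list fold ranged from 0.890 to 1.06 for anterior head and brain patterning, 1.55 to 1.62 for germ line, 0.993 to 1.01 for neuron identity transcription factors and 0.902 to 1.11 for proteasome. The density fold ranged from 1.03 to 1.04 for 2R.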

Other observations

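The tests in this part were chosen after the data were seen. A CTCF-type core, AGRKGGCGC, stood in 2.89% of summit windows and 0.43% of matched windows (odds ratio 6.74, 95% interval 4.36 to 10.4, Fisher's exact test p = 2.38e-25). CTCF is an insulator protein. In windows at TSS peaks it stood in 2.21%, against 0.53% at the same offset from a TSS with no summit within 1000 bp (odds ratio 4.17, Fisher's exact test, adjusted p = 2.45e-07). Those control windows were not matched on GC. In that comparison TAATNNNATTA was also more frequent in the peaks (2.71% against 1.30%, odds ratio 2.10, exact adjusted p = 0.00105), as was TAATNNATTA (2.64% against 1.62%, odds ratio 1.64, adjusted p = 0.0314), while TAATTA (odds ratio 1.12, adjusted p = 0.257) did not pass. Over all replicated peaks against windows matched on GC, neither palindrome passed (odds ratios 1.25 and 1.24).

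Mitochondrial ribosomal protein genes gave 3 of the 15 strongest peaks, yet as a list they did not pass the threshold. Of 73 genes, 16 (21.9%) were nearest to a peak, against 12.3 ± 3.16 in territory-matched random lists (fold 1.30, permutation p = 0.33).

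Of the replicated peaks held by the replicate 1 set and not by that of replicate 2, 145 of 223 (65.0%) lay at a TSS, against 661 of 1344 (49.2%) held the other way round. These shares describe both libraries, and the difference was not tested, since each side rests on 1 library.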
